A study of Mus musculus with 14 samples.

How the data were processed

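Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to mm10 and assigned to genes with featureCounts. The annotation, the strand setting and any filter on low values were not stated in those notes. The deposited values used here were raw counts per gene, 1 column per library, that the authors had not normalised: they were whole numbers, with totals of 18214415 to 24048281 per library. Per the file headers, the table also held 42 columns of per-sample values on other scales and a comparison of the authors, which were not used here. The table listed 12421 genes, each with at least 1 CPM in at least 2 libraries. Genes are named by the symbols and Ensembl identifiers of the table, with positions from GENCODE M21, in which 12379 of the 12421 identifiers were found, 11856 of them with the same symbol. Per the labels' protocols, RNA with an integrity number above 8 was made into libraries with the NEBNext Ultra II kit.

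The tumour number in the sample titles pairs the libraries without and with Dox, and the series design describes the tumours before and after Dox. As a check of this pairing, each library's deviation from its group mean was correlated, across genes, with that of its partner. The correlation was 0.645, 0.716 and 0.563 in VTL-44, VTL-33 and VTL-81, and 0.188, 0.0166 and 0.151 in VTL-153, VTL-25 and VTL-21.

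Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default filter on low counts (minimum count 10), robust quasi-likelihood fits and Benjamini-Hochberg adjustment over all genes of a comparison, with a threshold of 0.05. All adjusted p for genes come from this test unless another tool is named. The 12 libraries of the 6 tumours sequenced both ways were fitted together with tumour as a block and a Dox term for each class. Comparisons between classes used the 8 libraries without Dox or the 6 with Dox. Dox comparisons are with minus without Dox, and class comparisons are the first-named class minus the other. CPM used library sizes scaled by TMM factors.

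The 31 gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 240 tests with at least 3 measured members, and again with an estimated correlation and with fry. The named genes were Lmo2 and Ikzf1, and the 10 genes raised most and the 10 lowered most among those past the threshold. These also had a mean log2 CPM of at least 2 and moved the same way in every tumour, or had groups that did not overlap. Receptor segments, predicted genes, pseudogenes and sex-linked genes were left out of the top 10. From each list up to 4 members past the threshold were named. For the difference of Dox responses, the Dox average and the comparison with Dox the top was 5 genes. Where fewer than 5 genes passed in a direction, up to 5 with the smallest p were named as not passing. These had to meet the same conditions on level and direction. Values per tumour could be given for the Ikaros family, T-ALL tumour suppressor, T-ALL transcription factor and sex-linked genes. The groups, tests, lists, this rule and most alternatives were chosen before the data were examined.

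Alternatives were RLE size factors, DESeq2 1.42.0, limma voom, no filter, a minimum count of 50, fits that were not robust, receptor segments left out, no replicate block, 1 fit of all 14 libraries with tumour as a random effect, and each tumour left out in turn. Only leaving out VTL-44 and VTL-81 together was added after the data were seen. Where a tumour left out leaves 1 dependent tumour, that tumour is assumed to vary like the others. Exact 95% counting intervals were used where a group held 1 to 3 counts, and a floor of 3 counts over the group where it held 0.

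The tests were tested on simulated data with the same groups, in which 100 genes changed 2-fold and 100 changed 8-fold. For Dox in the evolving tumours edgeR recovered 14% of the 2-fold and 75% of the 8-fold changes and called 6 unchanged genes, against 49%, 89% and 76 for DESeq2. For independent against dependent tumours edgeR recovered 4% and 60%, with 2 unchanged genes called, and for independent against evolving tumours 11% and 65%, with 4. For the comparison with Dox it recovered 7% and 75%, with 6. The simulated tumours did not differ in their baselines, and each gene had the same spread in both classes. In the data, partners matched less closely in the evolving than in the independent tumours. The simulation could not show errors that come from this, so its rates may not hold for the data.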

Results

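RNA sequencing measured the transcripts of 14 libraries from 8 mouse T-cell acute lymphoblastic leukaemias of the VTL model, in which Lmo2 is the inducing oncogene. Per the labels' protocols, donor tumour cells were sorted by CD45.1 and CD45.2 from the spleens of Rag1-deficient mice into which each leukaemia had been transplanted. The labels divide the tumours by their relation to Lmo2 into 2 dependent (VTL-19 and VTL-24), 3 evolving (VTL-21, VTL-25 and VTL-153) and 3 independent (VTL-33, VTL-44 and VTL-81). Every tumour had 1 library from mice without doxycycline (Dox), and the evolving and independent tumours each had 1 more from mice given Dox in food at 600 mg/kg. Replicates within a group carried separate tumour numbers. VTL-25 and VTL-153 without Dox nevertheless matched closely, with 2 genes above 20 CPM in one and below 0.5 CPM in the other, against 15 to 116 for the other pairs of tumours without Dox. The deposited counts covered the listed genes and summed to between 18214415 and 24048281 per library. Mitochondrial genes held 1.62% to 6.01% of the counts. Levels below are CPM with the SD over tumours. Changes are log2 fold changes with an approximate SE, the size of the change divided by the square root of its quasi-likelihood F statistic. Where a group held few counts this SE is inexact and can be too small.

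Lmo2 (ENSMUSG00000032698, chromosome 2, 103957986 to 103981878 on mm10), a transcriptional cofactor of blood progenitors, was lower with Dox in each of the 6 tumours sequenced both ways. The series design speaks of activation by Dox, and the labels do not say which way Dox acts on the Lmo2 transgene, so that with and without Dox are used here only as the labels give them. Lmo2 stood at 708, 515 and 303 CPM without Dox in the evolving tumours VTL-153, VTL-25 and VTL-21, and at 0.405, 0.198 and 3.24 CPM with Dox. The independent tumour VTL-33 had 600 CPM without Dox and 1.32 CPM with it, whereas VTL-44 had 9.28 and 4.09 CPM and VTL-81 had 27.2 and 8.46 CPM. The dependent tumours VTL-24 and VTL-19 had 142 and 120 CPM. The log2 change with Dox was −8.98 (SE 1.95, n = 3 tumours) in the evolving tumours, with an adjusted p of 0.0782, and −3.10 (SE 1.71, n = 3) in the independent tumours, with an adjusted p of 1. The difference between these changes was 5.88 (SE 2.66, adjusted p = 0.568). Neither change nor the difference passed edgeR's test. By DESeq2 the change in the evolving tumours passed (adjusted p = 1.14e-09), as it did by edgeR without VTL-33 (adjusted p = 0.0388), and over all alternatives that adjusted p ran up to 0.246. The difference also passed by DESeq2 (6.78, adjusted p = 0.0235, against up to 1 over the alternatives), and it was 3.27 by limma voom, 3.10 with no replicate block and 0.20 without VTL-44 and VTL-81. In the independent tumours the estimate was −1.45 without VTL-33, −5.03 without VTL-44 and −4.90 without VTL-81, and it was −5.57 by limma voom, −5.53 with no replicate block and −8.82 without VTL-44 and VTL-81.

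Ikzf1 (ENSMUSG00000018654, chromosome 11, 11685003 to 11772926), which encodes the lymphoid transcription factor Ikaros named in the series title, was abundant in all 14 libraries, at 833 to 2403 CPM. Counts per gene do not show mutations, isoforms or protein, so these levels do not tell whether Ikaros was functional. Its mean level without Dox was 1201 ± 351 CPM in the dependent tumours (SD, n = 2), 1103 ± 275 CPM in the evolving tumours (n = 3) and 1214 ± 247 CPM in the independent tumours (n = 3). Independent and dependent tumours differed by 0.02 on the log2 scale (SE 0.29, adjusted p = 0.988), and independent and evolving tumours by 0.14 (SE 0.26, adjusted p = 0.844). These differences turned to −0.15 and −0.02 without VTL-33, and the former to −0.26 without VTL-19. With Dox the level moved in opposite directions in VTL-25, from 952 to 2403 CPM, and in VTL-153, from 1421 to 833 CPM. The log2 change with Dox over the evolving tumours was 0.23 (SE 0.37, adjusted p = 0.836) and was −0.32 without VTL-25. Ikzf3, which encodes the related factor Aiolos, stood at 50.1 to 191 CPM in the evolving tumours without Dox and at 404 to 618 CPM with Dox, and was higher with Dox in all 3. That log2 change of 2.54 (SE 0.48) had an adjusted p of 0.0556 over all genes, and Ikzf3 was the 1 of 5 Ikaros family genes that rose when adjusted over the list alone.

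**Figure D1:**
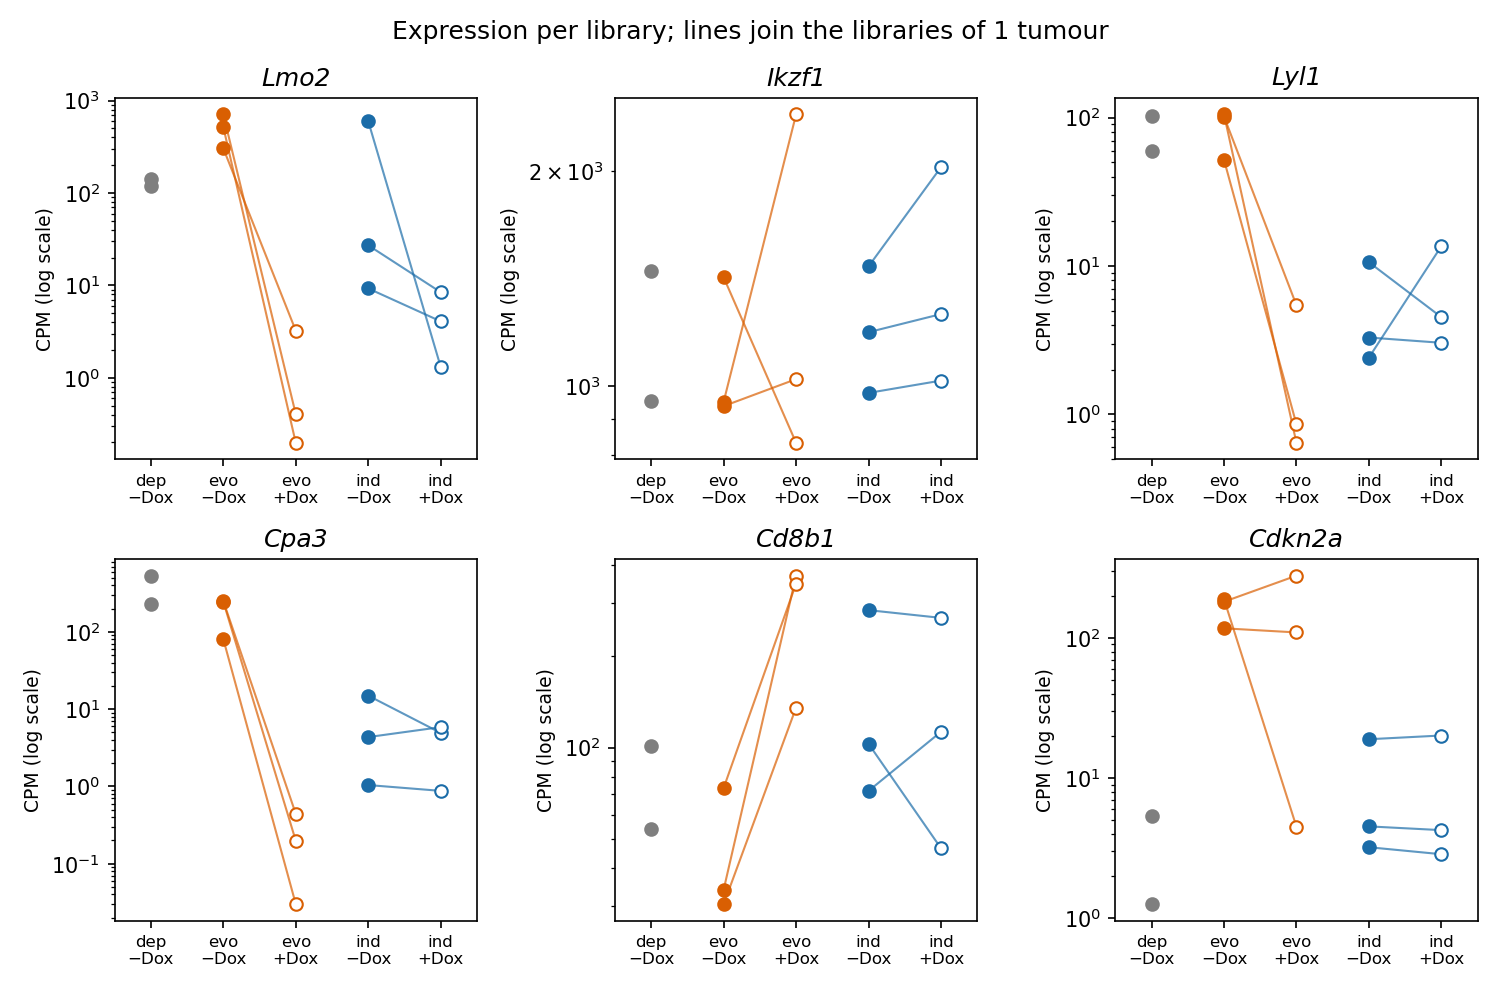
Levels of selected genes in each library (log axis, CPM) in dependent (dep), evolving (evo) and independent (ind) tumours without and with Dox, with 1 point per library and a line joining the libraries of 1 tumour; values below 0.03 CPM are drawn at 0.03. Lmo2 stood at 303 to 708 CPM in the evolving tumours without Dox and at 0.198 to 3.24 CPM with Dox.

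Over the 1000 most variable genes, the evolving and dependent tumours without Dox lay together at 47.2 to 67.9 on the axis that held 31.0% of the variance. The evolving tumours with Dox lay between −21.6 and −6.52 on that axis. The 6 libraries of the independent tumours lay between −56.9 and −25.1, with or without Dox. On the next axis, with 17.1% of the variance, VTL-153 and VTL-25 with Dox lay at 76.9 and 58.4, apart from VTL-21 with Dox at −9.26 and from the independent libraries at −43.5 to 17.2.

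**Figure D2:**
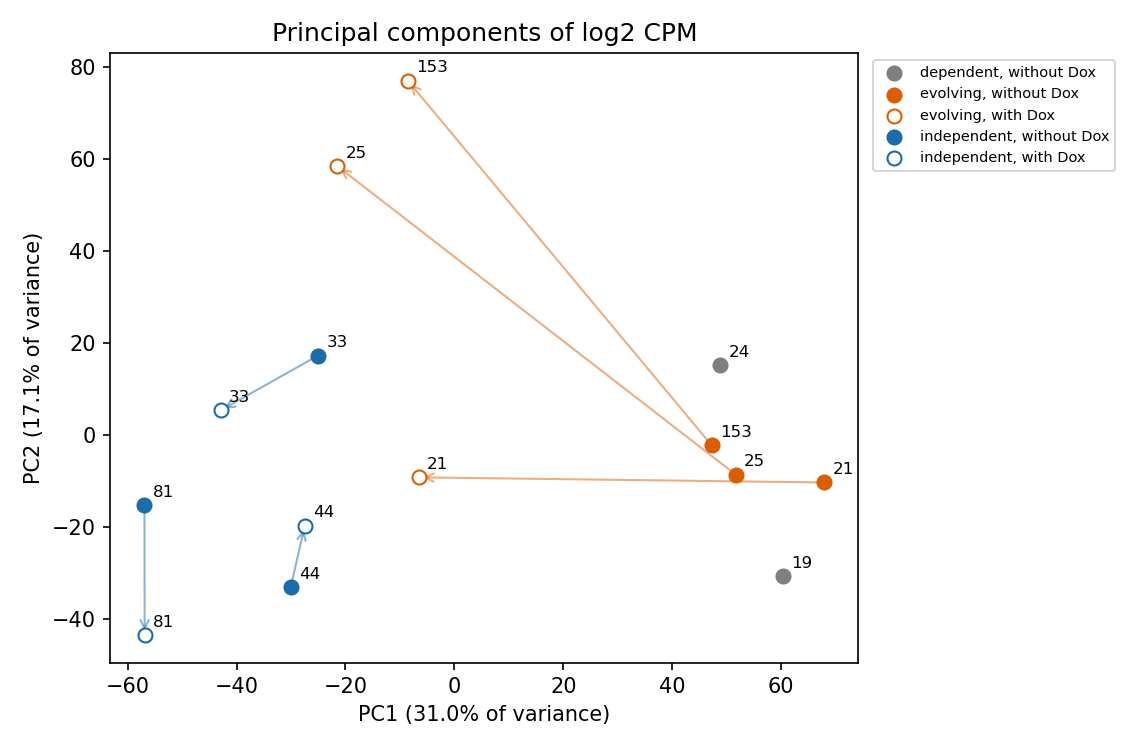
Principal components of log2 CPM over 1000 genes, with 1 point per library, coloured by tumour class and Dox and marked with the tumour number. The horizontal component (31.0% of the variance) runs from −56.9 in an independent tumour to 67.9 in an evolving tumour without Dox.

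The libraries of the evolving tumours without and with Dox were compared to ask what differed with Dox in tumours of that class. In VTL-25 the leading T cell receptor beta segment was Trbv24 without Dox and Trbv5 with it, so that this pair may compare different clones. In VTL-21 Trbv24 led both libraries, but the segment after it was Trbv13-1 without Dox and Trbv13-2 with it. The clones of that pair may therefore differ in part as well. Cpa3, a carboxypeptidase of mast cells and early progenitors, dropped from 192 ± 96.8 to 0.213 ± 0.221 CPM (log2 change −9.87, SE 0.66, n = 3 tumours). Hhex and Lyl1, transcription factors active in early progenitors, fell as well, with log2 changes of −7.52 (SE 1.24) and −5.72 (SE 0.95). Erg, an ETS transcription factor of haematopoietic stem cells, went from 2428 to 3 counts, a ratio of 726 (95% exact counting interval 248 to 3524). Ctla4, an inhibitory receptor of T cells, rose from 0.805 ± 0.776 to 47.0 ± 58.1 CPM (log2 change 5.47, SE 0.49). Il2rb, a chain of the interleukin receptors that signal through STAT proteins, rose by 5.40 (SE 0.75). Cd28, the main costimulatory receptor, rose from 44.3 ± 18.7 to 252 ± 115 CPM (log2 change 2.45, SE 0.28). Cd8b1, a chain of the CD8 coreceptor, rose from 45.9 ± 23.97 to 285 ± 130 CPM.

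Further genes raised in all 3 evolving tumours included Sdc1, a cell-surface proteoglycan, from 5.46 ± 3.98 to 166 ± 71.3 CPM, and Adam19, a membrane metalloprotease, from 7.56 ± 6.20 to 403 ± 441 CPM. P3h4 and Fkbp10, which act in collagen maturation, rose by 5.86 (SE 0.81) and 6.15 (SE 0.99). Col1a2, a collagen chain made by fibroblasts, rose from 0.0767 to 5.77 CPM, Trpm1, an ion channel, from 0.357 to 14.5 CPM, Ifi202b, an interferon-inducible gene, from 0.795 to 32.4 CPM, and Mical2, an actin-oxidising enzyme, from 0.190 to 7.25 CPM. Mdga1, a membrane-anchored adhesion protein, fell from 78.7 ± 59.4 to 0.198 ± 0.0981 CPM (log2 change −8.47, SE 0.31). Plagl1, an imprinted zinc finger gene, fell from 108 ± 53.8 to 0.246 ± 0.383 CPM, and Chil5, a chitinase-like protein, from 80.5 ± 51.1 to 0.2003 ± 0.136 CPM. The group with Dox held only 1 to 3 counts of the remaining genes with the largest decreases. For these the ratios of the level without Dox to that with Dox, with 95% exact counting intervals, were 1313 (235 to 51890) for Gria2, a glutamate receptor subunit, and 1111 (199 to 43915) for Armcx1. They were 912 (252 to 7537) for Zfp711, 836 (231 to 6911) for Adamts9 and 443 (151 to 2151) for Stard13. Such intervals cover counting error only.

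By edgeR's quasi-likelihood test 263 of 12360 genes passed with Dox in the evolving tumours, 136 higher and 127 lower, and 262 of them moved the same way in all 3 tumours. Among all tested genes 34.9% moved the same way in all 3, where chance gives 25% for unrelated tumours. VTL-25 and VTL-153 without Dox correlated at 0.973, so their changes may share a baseline and agree more often by chance. Changes were at least 2-fold for 245 of the 263. The spread was shared with the independent tumours, whose partners matched more closely, so that changes in the evolving tumours can be overstated. The count was 1314 by DESeq2, 439 by limma voom and 73 with no replicate block for tumour. It was 49 without VTL-25, 110 without VTL-153, 142 without VTL-44, 128 without VTL-33 and 162 without VTL-81, and of the 32 genes named for this comparison, 6 stayed past the threshold with each tumour left out in turn.

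Of the 15 tested markers of immature thymocytes, 4 fell with Dox in the evolving tumours (Cpa3, Hhex, Lyl1 and Erg) and none rose. The median log2 change of this list was −2.78, and 5 fell when adjusted over the list alone. Of 14 Lmo2-associated progenitor genes, 3 fell (Hhex, Lyl1 and Erg) and Lmo4, a relative of Lmo2, rose from 123 ± 59.3 to 320 ± 135 CPM. When adjusted over the list alone, 6 of these 14 fell and 1 rose, and the list's camera test gave an adjusted p of 0.0789. Among 16 markers of double-positive thymocytes, Cd8b1 rose, while 5 rose and 1 fell when adjusted over the list alone. Fyn, a kinase next to the T cell receptor, and Nr4a1, a nuclear receptor induced by its signal, rose among 17 genes of T cell receptor signalling by 1.56 (SE 0.16) and 2.10 (SE 0.38), and 3 rose when adjusted over the list alone. None of 12 genes of antigen presentation by MHC class I passed over all genes, and 5 fell when adjusted over the list alone. None of 23 interferon response genes or 11 erythroid markers passed either way. Single members of other lists also passed: Irs2, an adaptor of the insulin receptor, and Foxo1, a transcription factor, rose by 3.42 (SE 0.35) and 1.19 (SE 0.21). Hk1, a hexokinase, Cdk6, a cell cycle kinase, and Phlda3, a p53 target, fell, with log2 changes of −1.21 (SE 0.14), −1.24 (SE 0.22) and −2.57 (SE 0.46).

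The camera test with a preset correlation called the immature thymocyte (adjusted p = 0.00115), interferon response (0.000104) and MHC class I (0.000514) lists lower with Dox in the evolving tumours. It called the double-positive thymocyte (0.0287), T cell receptor signalling (0.0155) and erythroid (0.00272) lists higher. Each of these 6 lists had an adjusted p = 0.938 with an estimated correlation. Summed over their list, erythroid markers were higher with Dox in each evolving tumour, at 365, 475 and 481 CPM against 183, 222 and 311 CPM in VTL-153, VTL-25 and VTL-21. Stromal markers were also higher in each, at 180, 271 and 202 against 155, 179 and 182 CPM. Myeloid markers went from 303 to 27.1 CPM in VTL-153 and from 341 to 29.9 CPM in VTL-25, but from 25.8 to 300 CPM in VTL-21. B cell markers went from 757 to 8653 CPM in VTL-21, from 248 to 770 CPM in VTL-25 and from 267 to 261 CPM in VTL-153. Over all lists and comparisons 53 of 240 tests were called, against 0 with an estimated correlation and 0 by fry's directional test.

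In the independent tumours no gene passed edgeR's test for a change with Dox. Genes with the smallest p under the naming conditions included Qsox2, a sulfhydryl oxidase. It stood at 63.2 ± 34.5 CPM without Dox and 40.3 ± 23.8 CPM with it (log2 change −0.68, SE 0.16, n = 3 tumours). Arhgef10l (−0.74, SE 0.18) and Ptp4a3, a phosphatase (−0.64, SE 0.17), were also lower with Dox. Runx2, a transcription factor of bone and T cell precursors, stood at 1.84 ± 2.11 CPM without and 5.06 ± 4.02 CPM with Dox (1.75, SE 0.49). Each of these 4 genes had an adjusted p of 1 and, as a condition for being named, the same direction in all 3 tumours. Over all tested genes 17.0% moved the same way in all 3, where chance gives 25%. At an unadjusted p under 0.05 there were 87 of 12360 genes, fewer than chance alone gives. DESeq2 and limma voom also called 0. The fit shared each gene's spread between both classes. Partners' deviations correlated at 0.563 to 0.716 in the independent tumours and at 0.0166 to 0.188 in the evolving tumours. Changes in the independent tumours can therefore be understated, and the count of 0 does not show that Dox changed nothing there. Among the lists, MYC and ribosome biogenesis genes had a median log2 change of −0.29 over 20 members, 19 of them negative, and erythroid markers one of 2.04 over 11 members, all positive (camera adjusted p = 3.16e-09 and 1.51e-10). Double-positive thymocyte markers, Notch targets and stress response genes were also called lower, with medians of −0.21, −0.05 and −0.30. Called higher were the myeloid, mitochondrially encoded and immediate early lists, with medians of 0.94, 0.44 and 0.16. Summed myeloid markers went from 316 to 3472 CPM with Dox in VTL-81 and from 112 to 293 CPM in VTL-33, but from 2359 to 1469 CPM in VTL-44. The mitochondrial share of counts likewise went from 1.62% to 5.73% in VTL-81 and from 4.25% to 6.01% in VTL-33, but from 4.92% to 2.31% in VTL-44. Summed erythroid markers were 280 and 368 CPM without and with Dox in VTL-81, 329 and 458 CPM in VTL-44, and 369 and 353 CPM in VTL-33. The sex-linked list was called higher although its median was −0.26 and its mean −0.07. No member of these 9 lists passed, over all genes or adjusted over the list alone, and each list had an adjusted p = 0.938 with an estimated correlation.

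The response to Dox itself differed between independent and evolving tumours for 15 of 12360 genes. Cpa3 and Mdga1 fell in the evolving tumours, with a difference (independent minus evolving) of 9.35 (SE 0.79, n = 3 tumours per class) and 7.80 (SE 0.49). The same held for Pcdh7, a protocadherin (9.61, SE 1.03), Nfix, a transcription factor of progenitors (4.87, SE 0.50), and Trim36, a ubiquitin ligase (3.43, SE 0.38). In the independent tumours none of these 5 passed, with estimates from −0.68 (Mdga1) to 2.08 (Pcdh7). Without Dox, these 5 already had lower estimates in independent than in dependent tumours, with log2 differences from −9.09 (Mdga1) to −2.29 (Nfix). Ctla4 and Icos, receptors of activated T cells, and Sdc1 rose in the evolving tumours, with differences of −5.51 (SE 0.64), −4.85 (SE 0.49) and −5.11 (SE 0.43). So did Foxb1, a forkhead transcription factor (−4.72, SE 0.45), and Smyd1, a methyltransferase (−6.14, SE 0.67). In the independent tumours none of these 5 rising genes passed, with estimates from −1.02 (Smyd1) to 0.03 (Sdc1). Without Dox they already had higher estimates in independent than in dependent tumours, from 0.92 (Ctla4) to 7.85 (Foxb1). Whether these starting levels account for the differences in response was not tested. Icos stood at 1.04 ± 0.734 CPM without and 29.6 ± 24.6 CPM with Dox in the evolving tumours, against 5.71 ± 4.17 and 5.41 ± 4.06 CPM in the independent tumours.

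All 15 genes of that difference moved one way in every evolving tumour relative to every independent tumour. So did 15.1% of all tested genes, where chance gives 10% for unrelated tumours. The adjusted p of the 10 named genes ran from 0.0135 to 0.0486. Immature thymocyte markers had a median difference of 2.55 over 15 members, with 1 passing over all genes (Cpa3) and 4 adjusted over the list alone. Lmo2-associated genes had a median of 2.56 over 14 members, with 0 passing and 5 adjusted over the list alone. Both lists were called by camera (adjusted p = 0.00189 and 0.0155), each with an adjusted p = 0.938 with an estimated correlation. The count of 15 became 549 by DESeq2, 67 by limma voom and 1 with no replicate block. It became 3 without VTL-153, 58 without VTL-21, and 0 by edgeR without VTL-25, VTL-44, VTL-33 or VTL-81, where 1045, 936, 829 and 980 genes had an unadjusted p under 0.05.

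Averaged over both classes, 18 of 12360 genes passed, 12 higher and 6 lower with Dox. Of these, 5 moved the same way in all 6 tumours, as did 3.25% of all tested genes, where chance gives 3.12% for unrelated tumours. These 5 were Susd4, an inhibitor of complement, and Lipa, the lysosomal acid lipase, which rose, and Mdga1, Igfbpl1 and Il9r, which fell. Il9r, the interleukin-9 receptor, stood at 358 ± 47.3 CPM without and 81.6 ± 31.3 CPM with Dox in the evolving tumours and at 191 ± 79.9 and 114 ± 35.3 CPM in the independent tumours (average log2 change −1.46, SE 0.17, adjusted p = 0.0499). Lipa stood at 101 ± 46.0 and 271 ± 66.9 CPM in the evolving tumours and at 153.2 ± 123 and 224 ± 173 CPM in the independent tumours (1.03, SE 0.12, adjusted p = 0.0499). Cpa3 also passed, at −5.20 (SE 0.40). The immature thymocyte, interferon response and MHC class I lists were called lower, with medians of −0.91, −0.42 and −0.26, and the T cell receptor signalling, PI3K-AKT and FOXO, and erythroid lists higher, with medians of 0.17, 0.34 and 1.31, each with an adjusted p = 0.938 with an estimated correlation. The count of 18 became 510 by DESeq2, 79 by limma voom, 9 without a filter, 45 with a minimum count of 50 and 2 with no replicate block. It became 2 without VTL-153, 99 without VTL-21, 1 without VTL-44, 3 without VTL-33, 6 without VTL-81, and 0 by edgeR without VTL-25, where 1042 genes had an unadjusted p under 0.05.

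Without Dox, evolving and dependent tumours were compared for differences that precede Dox. As VTL-25 and VTL-153 without Dox correlated at 0.973, the evolving group may hold fewer than 3 independent tumours, and its spread may be understated. Mtx3, a mitochondrial outer membrane protein, stood at 6.65 ± 1.40 CPM in the evolving tumours (n = 3) and 25.8 ± 3.21 CPM in the dependent tumours (n = 2), a log2 difference of −1.95 (SE 0.22) with the lowest adjusted p of the comparison, 0.240. Zbed3 stood at 8.32 ± 1.48 against 27.3 ± 8.00 CPM and Abcg2, an efflux transporter of stem cells, at 0.295 ± 0.0391 against 6.31 ± 2.38 CPM. Map7, a microtubule-binding protein, stood at 95.02 ± 13.5 against 29.9 ± 13.2 CPM. The tumour suppressor gene Cdkn2a stood at 117, 182 and 190 CPM in VTL-21, VTL-25 and VTL-153 and at 5.41 and 1.26 CPM in VTL-19 and VTL-24 (log2 difference 5.61, SE 1.08, adjusted p = 0.814). It was the 1 of 24 T-ALL tumour suppressors that was higher when adjusted over the list alone. No gene passed edgeR's test over 12348 genes, 419 had an unadjusted p under 0.05, limma voom called 0 and DESeq2 64. Without VTL-33 edgeR called 1 gene. The mitochondrially encoded mRNAs (median −0.91 over 7 members, all negative) and integrated stress response genes (median −0.74 over 17) were called lower by camera. The S phase, G2 and M phase, interferon response and MHC class I lists were called higher, with medians of 0.25, 0.18, 0.52 and 0.14. No member of these 6 lists passed, and each list had an adjusted p = 0.938 with an estimated correlation.

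Independent tumours differed from dependent tumours without Dox at Foxb1, which stood at 24.4 ± 3.37 CPM in the independent tumours (n = 3) and 0.102 ± 0.0784 CPM in the dependent tumours (n = 2; log2 difference 7.85, SE 0.61, adjusted p = 0.00851). Arhgef3 was higher by 1.32 (SE 0.13). Armcx1, a mitochondrial protein encoded on the X chromosome, had 0 counts over the independent tumours and 23.1 ± 5.02 CPM in the dependent tumours, at least 511-fold lower against a floor of 3 counts over the group. Armcx4, of the same gene family, was lower (log2 difference −9.54, SE 0.58), as were Pcdh7 (−8.87, SE 0.76) and Fat4, an atypical cadherin (−7.98, SE 0.83). Sstr2, a somatostatin receptor, stood at 0.349 ± 0.0782 against 60.4 ± 14.2 CPM, P2rx7, an ATP-gated channel, at 49.6 ± 5.68 against 401 ± 224 CPM, and Abcb10, a mitochondrial transporter, at 10.5 ± 3.41 against 72.8 ± 8.19 CPM. Npc1, a cholesterol transporter, and Ube2w, a ubiquitin-conjugating enzyme, were lower, with log2 differences of −1.43 (SE 0.14) and −1.41 (SE 0.15). The adjusted p of these 11 genes ran from 0.00598 to 0.0343.

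Between independent and dependent tumours 12 of 12348 genes passed, 2 higher and 10 lower, and the groups did not overlap for any of the 12. Groups did not overlap for 27.7% of all tested genes, and chance alone gives 20% for 3 against 2 tumours. The count became 791 by DESeq2, 27 with all 14 libraries in 1 fit, 2 without VTL-153, 5 without VTL-25, 73 without VTL-44 and 23 without VTL-81, and limma voom called 0, with 1396 genes at an unadjusted p under 0.05. No immature thymocyte marker passed over all genes and 4 of 15 were lower when adjusted over the list alone (median −0.58, camera adjusted p = 0.0155, adjusted p = 0.938 with an estimated correlation). Myeloid markers had a median log2 difference of 2.43 over 19 members, all positive, with none passing (camera adjusted p = 0.00202). The G2 and M phase, nuclear oxidative phosphorylation, and immediate early lists were also called higher, with medians of 0.39, 0.26 and 0.32 and no member passing. Each of these 4 lists had an adjusted p = 0.938 with an estimated correlation. Summed myeloid markers stood at 2359 CPM in VTL-44, 316 CPM in VTL-81 and 112 CPM in VTL-33, against 155 and 46.4 CPM in VTL-19 and VTL-24.

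Independent tumours were also compared with evolving tumours without Dox. VTL-25 and VTL-153 without Dox correlated at 0.973, so the evolving group may hold fewer than 3 independent tumours. Its SD, and the SE and adjusted p of this comparison, may then be too small. Foxb1 stood at 24.4 ± 3.37 CPM in the independent tumours and 0.880 ± 0.222 CPM in the evolving tumours (n = 3 each; log2 difference 4.79, SE 0.42). C1qtnf6, a secreted protein, Arhgap21 and Timp2, a metalloprotease inhibitor, were higher by 6.03 (SE 0.81), 5.52 (SE 0.74) and 2.11 (SE 0.28). Malt1, a protease of antigen receptor signalling, stood at 49.4 ± 5.30 against 18.1 ± 1.92 CPM, Bcl9l, a cofactor of beta-catenin, at 48.1 ± 2.76 against 18.8 ± 3.16 CPM and Elk3, an ETS factor, at 48.5 ± 2.54 against 23.2 ± 2.64 CPM. Arhgef3, Mtx3 and Zbed3 were higher by 1.47 (SE 0.12), 1.98 (SE 0.21) and 1.96 (SE 0.26). Armcx1 had 0 counts in the independent tumours and was at least 409-fold lower against a floor of 3 counts over the group. Fat4, Armcx4, Sstr2 and Pcdh7 were lower, with log2 differences of −9.09 (SE 0.84), −9.05 (SE 0.56), −7.47 (SE 0.53) and −7.08 (SE 0.71). Arhgap6, Osbpl1a, Sytl2, Abcb10 and P2rx7 were also lower, with log2 differences of −7.31, −5.598, −4.64, −2.83 and −2.30.

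Over 12348 genes, 11 were higher and 21 lower in the independent than in the evolving tumours without Dox, 1 of them a T cell receptor segment (Trbv13-1), with adjusted p for the named genes from 0.00434 to 0.0488. The groups did not overlap for any of the 32. They also did not overlap for 23.5% of all tested genes, where chance gives 10% for 3 against 3 unrelated tumours. The count of 32 became 1068 by DESeq2 and 7 by limma voom, and 3 without VTL-153, 3 without VTL-25, 18 without VTL-21, 144 without VTL-44, 17 without VTL-33 and 16 without VTL-81. Of the 20 genes named for this comparison, 2 stayed past the threshold with each tumour left out in turn.

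Between independent and evolving tumours without Dox, the immature thymocyte list was called lower by camera (median −1.28, adjusted p = 0.00314), with 0 of 15 members passing and 4 lower adjusted over the list alone. Interferon response genes had a median of −0.86 over 23 members (adjusted p = 6.57e-05), of which 2 were lower adjusted over the list alone, and MHC class I genes one of −0.50 over 12 members, all negative (adjusted p = 0.000543). Mitochondrially encoded mRNAs and nuclear oxidative phosphorylation genes were called higher, with medians of 0.81 and 0.25, while the mitochondrial share was 1.62% in VTL-81 against 4.25% and 4.92% in VTL-33 and VTL-44. Markers of other cell types were called higher as well: myeloid (median 2.24, 19 of 19 positive), NK and innate lymphoid (median 2.18) and stromal (median 2.74), with 1 member passing, adjusted over the stromal list alone. Each of these 8 lists had an adjusted p = 0.938 with an estimated correlation. Lyl1 and Hhex stood at 2.41 to 10.6 and 0.478 to 3.13 CPM in the independent tumours, lower than in the evolving tumours with log2 differences of −3.99 (SE 0.64) and −4.92 (SE 0.79), each with an adjusted p of 0.0607 over all genes.

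With Dox, independent and evolving tumours were compared to ask what still differed once both had received it. Rag1 and Rag2, which encode the recombinase of antigen receptor genes, stood at 166 ± 26.5 and 8.27 ± 2.69 CPM in the independent tumours and 841 ± 96.3 and 33.3 ± 6.19 CPM in the evolving tumours (n = 3 each). Their log2 differences were −2.35 (SE 0.19, adjusted p = 0.0948) and −2.02 (SE 0.32, adjusted p = 0.939). C1qtnf6 stood at 63.3 ± 52.0 against 1.43 ± 0.773 CPM (adjusted p = 0.974) and Foxb1 at 23.5 ± 7.65 against 24.1 ± 14.9 CPM. No gene passed edgeR's test over 12093 genes, 573 had an unadjusted p under 0.05, limma voom called 1 and DESeq2 94. Without VTL-21 edgeR called 4. The double-positive thymocyte list was called lower (median −0.53, all 16 negative, camera adjusted p = 8.08e-08), with 0 members passing over all genes and 2 lower adjusted over the list alone, and had an adjusted p = 0.692 with an estimated correlation. MYC and ribosome biogenesis and interferon response genes were also called lower, with medians of −0.23 and −0.18. The Lmo2-associated, mitochondrially encoded, myeloid and stromal lists were called higher, with medians of 1.36, 1.00, 2.31 and 2.32, and these 6 lists each had an adjusted p = 0.938 with an estimated correlation. Summed myeloid markers with Dox stood at 1469 CPM in VTL-44, 3472 CPM in VTL-81 and 293 CPM in VTL-33, against 27.1, 29.9 and 300 CPM in VTL-153, VTL-25 and VTL-21.

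The 263 genes that changed with Dox in the evolving tumours were compared with the difference between independent and dependent tumours without Dox, which uses neither library of an evolving tumour for its estimate. Of the 127 genes that fell with Dox, 120 had a lower estimate in independent than in dependent tumours, and of the 136 that rose, 130 had a higher one, so that 250 of the 261 genes tested in both comparisons (95.8%) had the same sign. Scn8a and Ramp3, which rose, were not tested between independent and dependent tumours. Armcx1 was lower and Foxb1 higher in both tests. Cpa3, Erg and Sdc1 shared the sign only, with adjusted p of 0.0950, 0.138 and 0.192 between independent and dependent tumours. This comparison was chosen after the values were seen, and genes are not independent replicates. The share of matching signs over all tested genes is not given here. By the difference of mean log2 CPM the signs matched for 97.0% of the 263 genes, and other splits of those libraries reached up to 79.1%.

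**Figure D3:**
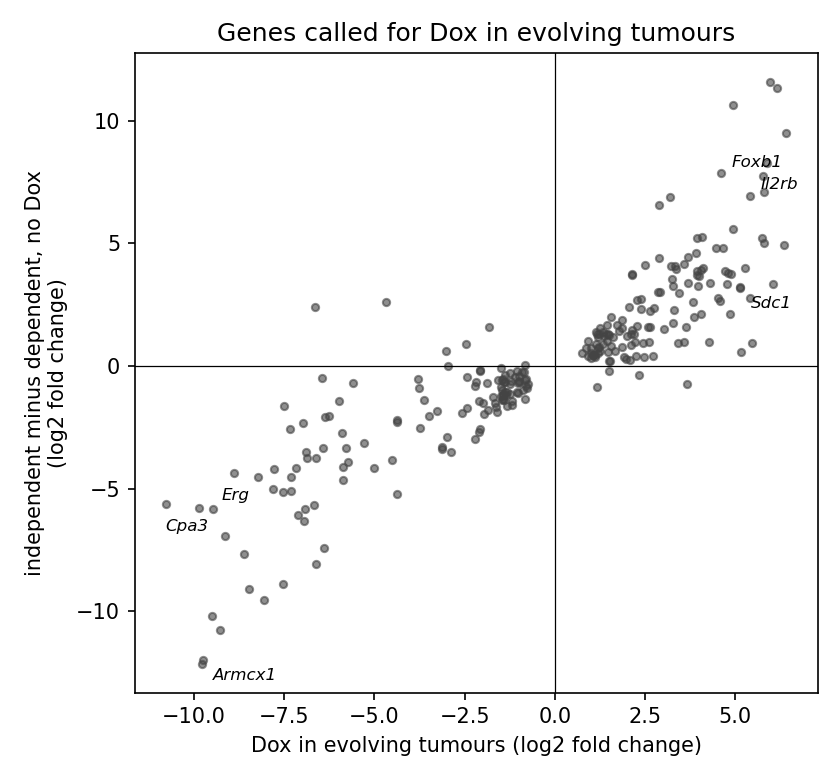
Each point is 1 of the 261 genes changed with Dox in the evolving tumours and tested in both comparisons, with its log2 change with Dox on the horizontal axis and its log2 difference between independent and dependent tumours without Dox on the vertical axis. Fitted values are drawn for all of them, also where a group held 0 to 3 counts. The signs match for 250 genes.

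T cell receptor beta chain variable segments, chosen after their values were seen, were compared between libraries. In the dependent tumours Trbv2 led, at 569 CPM in VTL-24 and 15.0 CPM in VTL-19. All listed beta variable segments of VTL-19 summed to 16.0 CPM beside 689 CPM of the constant segment Trbc2, so that the listed segments do not show the leading rearrangement of every library. Trbv24 led in the 3 evolving tumours without Dox, at 366, 238 and 242 CPM in VTL-153, VTL-25 and VTL-21, with Trbv13-1 following at 101, 59.6 and 39.6 CPM. With Dox, VTL-153 kept both segments at 345 and 119 CPM. In VTL-21 with Dox, Trbv24 stood at 421 CPM and Trbv13-2 came after it at 7.47 CPM. In VTL-25 with Dox, Trbv5 held 99.6% of the summed segments at 270 CPM, against 3.73 CPM of Trbv5 without Dox. The independent tumours led with the same segment without and with Dox, namely Trbv19 in VTL-44 (840 and 1007 CPM), Trbv24 in VTL-33 (326 and 369 CPM) and Trbv2 in VTL-81 (1229 and 1169 CPM).

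**Figure D4:**
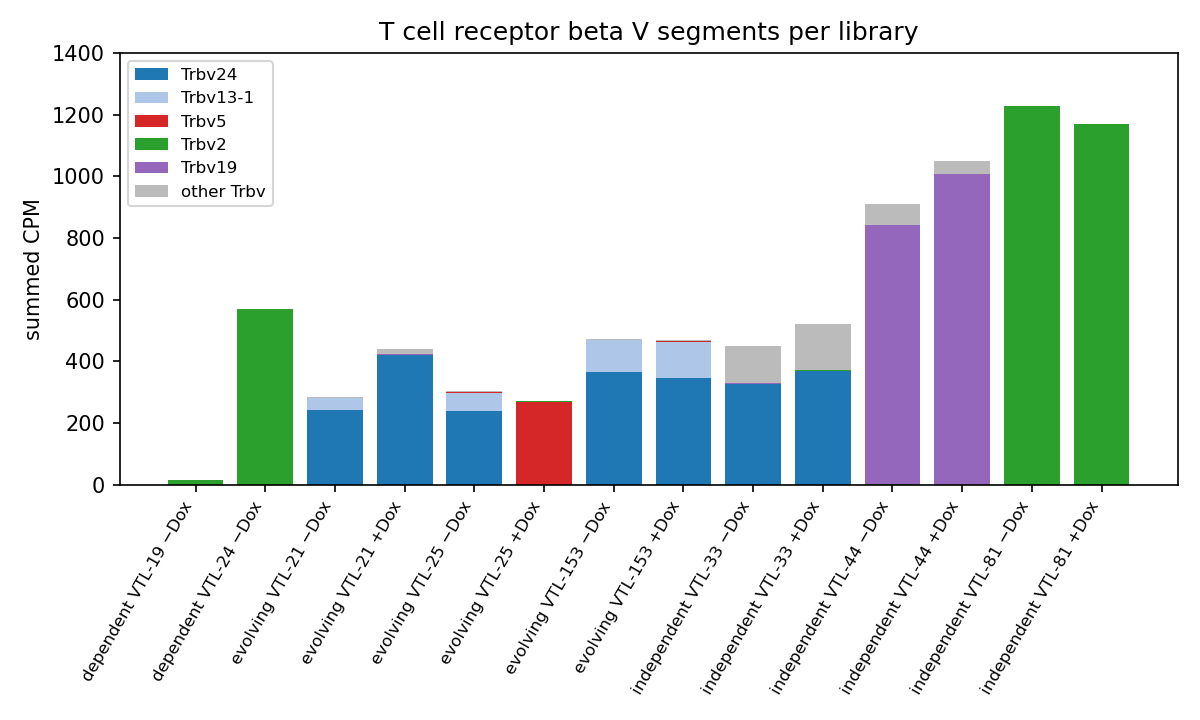
Summed CPM of T cell receptor beta variable segments in each library, stacked by segment. Trbv24 leads VTL-25 without Dox at 238 CPM and Trbv5 leads it with Dox at 270 CPM, while each independent tumour keeps its leading segment.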

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

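The tests of other splits of the samples were chosen before the results were seen, and all other tests in this part, on cell mixture, the VTL-25 and VTL-153 libraries and the match with independent tumours, were chosen only after the results were seen.

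The test of the difference in Dox response between independent and evolving tumours called 15 genes. Its 10 named genes were Pcdh7 (9.61), Cpa3 (9.35), Mdga1 (7.80), Nfix (4.87) and Trim36 (3.43), which fell with Dox in the evolving tumours, and Smyd1 (−6.14), Ctla4 (−5.51), Sdc1 (−5.11), Icos (−4.85) and Foxb1 (−4.72), which rose there, as log2 differences, and none of the 10 passed in the independent tumours. Trpm1 was higher with Dox in all 3 evolving and lower in all 3 independent tumours, with a difference of −6.57 that did not pass the test of the difference (adjusted p = 0.0845). For 6 lists camera called the difference: median log2 differences were 2.56 for Lmo2-associated progenitor genes, 2.55 for immature thymocyte markers, −0.67 for double-positive thymocyte markers, −0.46 for MYC and ribosome biogenesis, 0.57 for interferon response and 0.58 for MHC class I genes, each with an adjusted p = 0.938 with an estimated correlation. For the 10 named genes, the independent against dependent estimate without Dox already had the sign of their change in the evolving tumours. No group held enough samples to look for single outlying samples.

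The 15 genes were those of 1 of the 10 splits of the 6 tumours, and the highest of the other splits called 0, with too few splits for a share under 0.05. The same limit holds for the 263 genes of Dox in the evolving tumours (1 of 4 splits, highest other 3), the 0 genes of Dox in the independent tumours (4 of 4, highest other 0), the 32 genes of independent against evolving tumours without Dox (1 of 10, highest other 0) and the 0 genes with Dox (10 of 10, highest other 0). For Dox averaged over both classes, 7 of 32 splits called at least the 18 genes of the real one, up to 53. Of these 7, 6 were among the 8 splits that left the Dox labels of the 3 evolving tumours aligned and so kept the response of that class, and the other called 32. The counts follow this structure of the samples. As 7 of 32 is not a share under 0.05, the rule set beforehand reads this as chance being able to account for the 18 genes. However, most of these splits kept the response of the evolving tumours, so the test cannot tell chance from that response. Of the 24 splits that broke that response, 1 called at least 18 genes. Splits that exchanged Dox labels only in independent tumours mostly called as many genes or more. The 18 genes therefore do not show a response shared by both classes.

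In the evolving tumours, genes such as Cpa3 and Erg fell and others such as Ctla4 and Il2rb rose with Dox. In VTL-25, whose leading segment was Trbv24 without and Trbv5 with Dox, such changes may also hold differences between clones. The same may hold in VTL-21. Trbv24 led both of its libraries, but Trbv13-1 went from 39.6 CPM without Dox to at most 7.47 CPM with it. Whether clones account for such changes in any evolving tumour was not tested. Dilution by cells that lack T cell receptor signalling genes would lower those 17 genes as well. They had a median log2 change of 0.296 (quartiles 0.128 and 0.880, lowest −0.967 for Cd69). The fallen genes, which were selected for lying below 0, had a median of −2.57 and a 95th percentile of −0.843. This argues against such dilution as the only source of the decreases, unless the 17 genes rose in the tumour cells. Admixed T cells carry these genes too, so this test could not exclude them. For the increases, a larger share of other cells stays open. The reason is that 2 lists of other cell types, erythroid and stromal, had a higher sum in all 3 tumours with Dox. However, of their members only Col1a2 was among the genes that rose, and the cells had been sorted for donor CD45 markers. A hypothesis is that evolving tumours on Dox may move towards the profile of independent tumours: by the difference of mean log2 CPM, 97.0% of the 263 genes had the sign of the independent against dependent difference, against at most 79.1% over the other splits, with 10 splits, too few for a share under 0.05. On the principal component with 17.1% of the variance, VTL-153 and VTL-25 with Dox nevertheless lay at 76.9 and 58.4, outside the independent libraries at −43.5 to 17.2.

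The libraries of VTL-25 and VTL-153 without Dox matched more closely than any other pair of tumours without Dox: 2 genes were above 20 CPM in one and below 0.5 CPM in the other, against 15 to 116. Between the libraries of 1 tumour without and with Dox there were 0 to 1 such genes in the independent and 42 to 61 in the evolving tumours, with 53 in VTL-25. The libraries without Dox were not 1 library under 2 labels, as their counts differed by a chi-square of 52.9 per degree of freedom, and a wrong label on a library with no VTL-25 material is argued against by Trbv5, at 3.73 CPM (93 counts) in VTL-25 without Dox and at most 0.759 CPM in any other tumour. A wrong label with carried-over material could account for it, since 11 genes of VTL-25 with Dox stood at a median of 2.11% (quartiles 1.71% and 2.53%) of their level with Dox, and a clone present in both tumours could as well, given the 2 genes. These last explanations cannot be told apart with 1 library per tumour and condition, and without VTL-25 the count of 263 genes was 49.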

How the results depend on the processing

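The settings listed were set in advance, except that leaving out VTL-44 and VTL-81 together was chosen only after the results were seen. All 79 named gene results past the threshold kept their direction under each of the settings run for them. The top genes had been named only if they moved the same way in every tumour or had groups that did not overlap. A change of direction was therefore unlikely from the start. Of the 79, 18 stayed past the threshold under every setting run for them that left out no tumour, and 10 with each tumour left out in turn. Depth limits genes with 0 to 3 counts in a group, for which the text gives bounds or counting intervals. The cause of other changes was not tested, and leaving out a tumour raised some counts and lowered others.

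DESeq2 called 1314 genes for Dox in evolving tumours, 510 for the Dox average, 549 for the difference in Dox response, 64 for evolving against dependent, 791 for independent against dependent, 1068 for independent against evolving tumours and 94 for the latter with Dox. It put Lmo2 past the threshold for Dox in evolving tumours (−9.75), for the Dox average (−6.36) and for the difference (6.78). Limma voom called 439, 79, 67, 0, 0, 7 and 1, the counts of 0 with 323 and 1396 genes at an unadjusted p under 0.05. With no replicate block for tumour the Dox counts were 73, 2 and 1. The Dox average had 9 genes without a filter and 45 with a minimum count of 50. With all 14 libraries in 1 fit, independent against dependent tumours had 27 genes. Without VTL-44 and VTL-81, the counts were 17 for Dox in evolving tumours, 0 for the average and 0 for the difference (567 and 423 with an unadjusted p under 0.05), and 9 for independent against evolving tumours.

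With each tumour left out, the counts ran from 49 to 347 for Dox in evolving tumours, 0 to 99 for the average, 0 to 58 for the difference, 0 to 1 for evolving against dependent, 2 to 73 for independent against dependent, 3 to 144 for independent against evolving and 0 to 4 with Dox. Lmo2 for Dox in evolving tumours ran from −10.999 to −8.16 and passed without VTL-33 (−9.07). Of 240 list tests, 0 were called with an estimated correlation and 0 by fry, against 53.

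Ikzf1 turned sign with single tumours left out: its log2 values ran from −0.32 to 0.72 for Dox in evolving tumours, −0.0621 to 0.46 for the average, −0.52 to 0.51 for the difference, −0.39 to 0.21 for evolving against dependent, −0.26 to 0.35 for independent against dependent, −0.0232 to 0.36 for independent against evolving and −0.33 to 0.62 with Dox. Its Dox difference was 0.24 without VTL-44 and VTL-81. Lmo2 in independent against dependent tumours was 0.695 in the main fit, −1.25 by limma voom and −1.27 with all 14 libraries. It ran from −2.84 to 1.26 with single tumours left out. In independent against evolving tumours Lmo2 was −1.26 in the main fit. It was 0.24 without VTL-44 and VTL-81, the only positive value over the settings.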

Other observations

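The values in this part were all picked out after the results were seen, and no test was run on them here.

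Cdkn2a, which encodes cell cycle inhibitors lost in many T-cell leukaemias, stood apart in VTL-153 by its change with Dox, from 190 to 4.502 CPM, while VTL-25 had 182 and 279 CPM and VTL-21 117 and 110 CPM. The independent tumours VTL-33, VTL-44 and VTL-81 had 3.21, 19.0 and 4.53 CPM without Dox and 2.87, 20.2 and 4.26 CPM with it. Notch1 was abundant in every library, at 1532 to 2910 CPM. Ikzf3 stood at 257 to 833 CPM over the 6 libraries of the independent tumours and at 39.6 and 102 CPM in the dependent tumours VTL-19 and VTL-24.

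B cell markers summed to 8653 CPM in VTL-21 with Dox and to 102 to 847 CPM in the other 13 libraries. Xist stood at 4.34 to 47.1 CPM in the libraries of VTL-33 and VTL-81 and at 759 to 2964 CPM in the other tumours. Ddx3y, a gene of the Y chromosome, stood at 95.4 and 145 CPM in VTL-81 without and with Dox and at 0 to 7.94 CPM in the other libraries.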
